A study of Mus musculus with 58 samples.

How the data were processed

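RNA and genomic DNA (gDNA) of insert libraries, and gDNA of sorted cells, were counted per insert in mouse embryonic stem cells. Per the labels' protocols, inserts of 175 nt were integrated 157 nt from the antisense start site at Pou5f1 or 102 nt from the start site at 14Rik, and RNA was reverse transcribed with a primer 221 nt or 287 nt downstream. Per the submitters' processing notes, reads were trimmed with cutadapt 1.14 and aligned with Bowtie2 2.3.4.3. RNA libraries were counted on unspliced and spliced references and gDNA libraries on unspliced references, per the file headers and names. The deposited counts are reads per reference as the authors counted them. Every count in the files is even (0 odd counts), as counting both mates of a pair would give. The deposited ratio values divide the RNA count of an insert by its gDNA count. In all 17 deposited ratio columns they equalled the counts up to 1 constant per library (1.17 to 2.57), and the lowest gDNA count among the values deposited was 20 to 98 by column. The deposited fraction (share) of spliced reads, which the authors call splicing efficiency, equalled the spliced count over all counts of the insert. The deposited sort-seq score is the authors' mean bin of an insert; 4 columns of the deposited tables were not used. How the spliced references were chosen is not given in the sources used here.

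Of 58 samples, 46 with count files were used. The other 12 (H3K4me3 ChIP-seq, TT-seq and PRO-seq, 4 each) were not analysed here. Libraries held 507182 to 94099800 reads on references, and 45.7% to 56.7% of the reads of a library had no reference. RNA was the sum of unspliced and spliced counts. Comparisons were fitted with edgeR 4.0.16 (quasi-likelihood test, TMM scaling) in R 4.3.3, with the kind of library and the screen as a block, on inserts with at least 50 reads in every gDNA library used. Chromatin RNA, run-on RNA and total RNA against each of them were tested in 1 fit of all 13 untreated Pou5f1 libraries. These share 1 estimate of the spread, since 2 libraries of a kind give almost none. A comparison of RNA with gDNA asks whether an insert's RNA share differs from its gDNA share. The locus and siRRP40 comparisons are interactions of that difference with the group. Calls had a Benjamini-Hochberg adjusted p under 0.05. Log2 RNA per gDNA per screen used a prior count of 2. Insert classes (with a spliced reference, without one, with 2 or more) were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over all classes and comparisons.

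Spliced shares were compared with edgeR on spliced and unspliced counts of inserts with at least 20 reads in each library. Sort-seq was fitted as a slope of abundance over 6 bins with the screen as a block, on inserts with at least 50 reads in every unsorted library and 100 over the bins of each screen. A count of 0 was set to 3 reads to give a fold or a percentage. Since every count is even, 3 read pairs would be more reads, so these values are nominal and not bounds. The choices of test, filter and alternatives, and the rule for the inserts named, were fixed before the data were examined. By that rule, the named inserts are those past the threshold with the largest changes in each direction that changed the same way in every screen and had a mean of at least 200 gDNA reads. The rule took 10 per direction for Pou5f1 total RNA, siRRP40 and the loci and 5 for each other comparison, and for spliced shares the 5 highest and the 5 with the largest change. At most 2 per direction are printed, since the files do not pair insert numbers with genes or sequences.

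Screen numbers were checked for pairing by correlating deviations from group means across inserts. Same-numbered RNA and gDNA libraries correlated at 0.363 to 0.564 at Pou5f1 (others at most 0.0714), 0.324 to 0.347 in siNT and 0.358 to 0.386 in siRRP40 cultures, and total with chromatin RNA at 0.206 to 0.408. At 14Rik they correlated at 0.038 to 0.339 and others at up to 0.043, and 2 of 3 RNA libraries correlated best with their own gDNA. The pairing there rests on the shared number and on the deposited ratios, which the authors formed from the same-numbered libraries. The letters of siNT and siRRP40 RNA libraries correlated at 0.0137 to 0.0231 and were not used as pairs.

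The tests were run on simulated data with 200 changed inserts and all others unchanged. In the real data 40.6% of inserts were called for Pou5f1 total RNA and 42.9% for 14Rik. Benjamini-Hochberg adjustment depends on that share, so the simulated recovery does not give the power of those comparisons. Of inserts changed 4-fold, 29.9% were recovered for Pou5f1 total RNA, 31.3% for chromatin RNA, 29.9% for run-on RNA, 11.9% for 14Rik, 16.4% for the loci and 64.2% for siRRP40. At 16-fold these were 81.8%, 72.7%, 71.2%, 60.6%, 75.8% and 97.0%. For spliced shares, 0% of 4-fold changes were recovered against run-on and chromatin RNA, and 13.6% and 33.3% of 16-fold changes. The noise of the spliced-share simulation was changed to log-normal odds, with the spread of the real replicates, after a first version recovered none, and 16-fold changes were added then. Alternatives were DESeq2 1.42.0, other size factors, other read minimums, unspliced reads alone, the fit without the block, the deposited ratios in limma (pseudocount 0.1), limma on log shares, and leaving out each replicate. Counts halved to read pairs were added after seeing the data. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.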

Results

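INSERT-seq places a library of short sequences behind one promoter and reads, for each insert, how much RNA it yields per integrated copy. The series applied it in mouse embryonic stem cells (F121-9, a hybrid line whose parental alleles can be told apart by sequence) to ask which transcribed coding and non-coding sequences let RNA polymerase II elongate. The library held 16461 inserts of 175 nt. At the first site, inserts sat 157 nt downstream of the upstream antisense start site of Pou5f1, the gene of the pluripotency factor Oct4, and just upstream of a gene for the red fluorescent protein mKate2. Pou5f1 lies on chromosome 17 from 35506032 to 35510777 (GRCm38, protein-coding). At the second site, in wild-type cells, inserts sat 102 nt downstream of the start of the long intergenic non-coding RNA gene 4930461G14Rik (chromosome 9, 58455173 to 58469623, GRCm38), here called 14Rik.

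Of 58 samples, 46 had count files. They were 17 RNA libraries, 14 genomic DNA (gDNA) libraries from the same cells, 12 libraries from cells sorted into 6 bins in 2 screens, and 3 libraries from unsorted cells. At Pou5f1 total (steady-state) RNA was read in 4 screens, RNA bound to chromatin in 2 of them (screens 2 and 3), and nascent RNA from a 15-minute nuclear run-on in 2 (screen 4 and a further screen 5). Total RNA was also read in 3 screens at 14Rik and in 3 cultures each 48 h after 40 nM control siRNA (siNT) or siRNA against RRP40 (siRRP40). H3K4me3 ChIP-seq, TT-seq and PRO-seq samples (4 of each) were not analysed here. RNA libraries held 2665226 to 94099800 reads on inserts, gDNA libraries 1991728 to 48334996 and sorted bins 507182 to 7437828. The files name inserts by number only and do not pair the numbers with genes, positions or sequences, so at most 2 inserts per direction are named in a comparison. Every level below is the RNA share of an insert relative to its gDNA share, and so relative to the typical insert of its library.

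The RNA levels of inserts correlated between replicate libraries, more so for total than for nascent or chromatin RNA. Across inserts with at least 50 gDNA reads, log2 RNA per gDNA correlated between siNT cultures with a mean Pearson r of 0.872 and between siRRP40 cultures with 0.858. The mean was 0.652 (range 0.604 to 0.754 over 6 pairs) between Pou5f1 total RNA screens and 0.709 (3 pairs) between 14Rik screens. Single inserts still varied: between Pou5f1 total RNA screens the median absolute difference in log2 RNA per gDNA was 0.76 to 0.95 by pair. The pair of run-on libraries gave 0.417 and the pair of chromatin libraries 0.410. These are correlations across inserts, which are not independent replicates. The spread between screens was larger at inserts with fewer reads: over the 4 Pou5f1 screens the median SD of log2 RNA per gDNA was 1.71 for inserts with a mean of 50 to 200 gDNA reads and 0.49 for inserts with over 2000.

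Total RNA at Pou5f1 differed widely between inserts. Of 10650 inserts tested, 4328 (40.6%) differed from the typical insert, 2462 higher and 1866 lower, and 2125 and 1801 of these by more than 2-fold. From the 5th to the 95th percentile, log2 RNA per gDNA ran from -3.09 to 2.06. The strongest rise was that of sequence_12550, with 214142 RNA reads against 2074 gDNA reads over 4 screens (log2 fold change 5.62, SE 0.32, adjusted p = 5.35e-05, edgeR quasi-likelihood test). Next came sequence_12189 (4.77, SE 0.48, adjusted p = 0.000293). Both have a spliced reference, and on unspliced reads alone their fold changes turned to -1.79 and -3.78 (adjusted p = 0.0825 and 0.0508). Among the inserts that fell were sequence_11448, with 112 RNA reads, all in 1 of the 4 libraries, against 2894 gDNA reads (41.2-fold lower on pooled reads, adjusted p = 0.00738), and sequence_15192, with 6 against 868 (231-fold lower on pooled reads, adjusted p = 0.00562). The call of sequence_15192 was lost without screen 1 (adjusted p = 0.0511). The count was 2888 without screen 1 and 2678 without screen 4. The split of higher and lower depends on the scaling: with plain library totals it was 1436 higher and 3573 lower.

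Inserts given a spliced reference yielded more RNA than the others. The deposited references give 2404 inserts (14.6%) at least 1 spliced form, which lacks 21 to 155 nt (median 100 nt), and 14057 inserts none. Spliced reads could be counted only at inserts with such a reference, so spliced RNA of the other inserts may be missing from their level. At Pou5f1, 643 of 1426 tested inserts with a spliced reference were higher than the typical insert and 113 lower, against 1819 and 1753 of 9224 without one. Their median log2 fold change was 0.84, against -0.24 for the rest. Screen by screen the gap between the class medians was 1.03 ± 0.21 (SD, n = 4; about 2.05-fold), and it was positive in all 4. The class was higher by camera's set test (adjusted p = 5.63e-12 with the preset correlation, adjusted p = 0.0861 with an estimated correlation). How the spliced references were chosen is not given in the sources used here. If these libraries served for it, the class is not independent evidence of its direction. On unspliced reads alone, which leaves out RNA of this class and of no other insert, the gap was -0.24 (adjusted p = 0.226).

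The excess of RNA was largest at inserts whose reads were mostly spliced. With the share taken from the siNT cultures and the level from the 4 untreated Pou5f1 screens, the median log2 RNA per gDNA was 0.29 ± 0.04 (SD, n = 4 screens) for 358 inserts under 1% spliced. It was 0.27 ± 0.14 from 1 to 10% (164 inserts), 0.39 ± 0.13 from 10 to 50% (267 inserts), 1.17 ± 0.28 from 50 to 90% (244 inserts) and between 1.71 and 3.08 in the 4 screens at 90% or more (340 inserts). Inserts without a spliced reference stood at -0.09 ± 0.06 (8373 inserts). Screen 4 gave the 3.08, and its levels correlated more with those of the siNT cultures (Pearson 0.793 to 0.805 across inserts) than with those of the other Pou5f1 screens (0.616 to 0.754). In screens 1, 2 and 3 the median at 90% or more was 2.61, 1.71 and 1.79. Within the class the level correlated with the siNT spliced share in every screen (Spearman 0.354 to 0.563 across 1373 inserts).

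**Figure D1:**
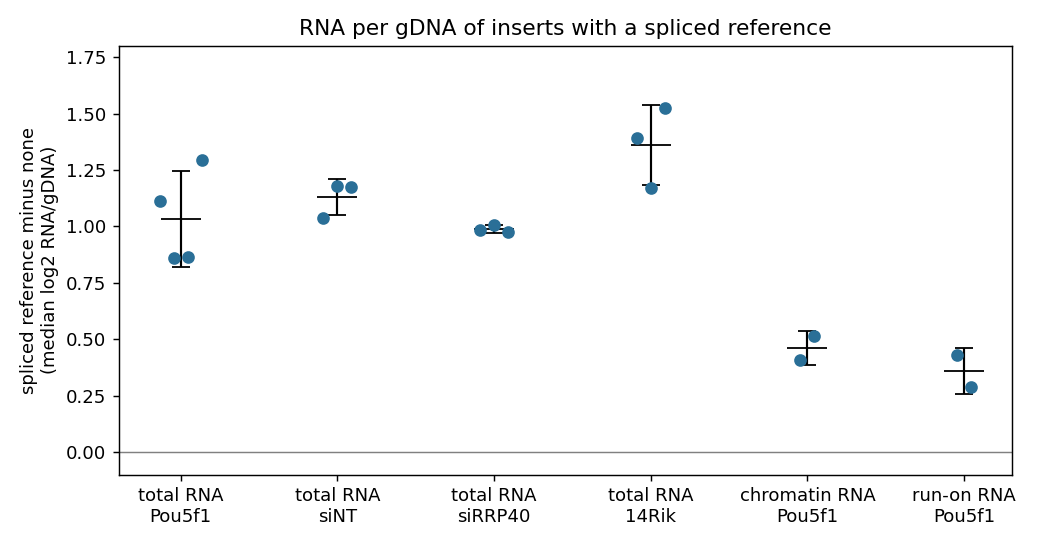
Difference in median log2 RNA per gDNA between inserts with and without a spliced reference, for each library (points), with the mean and SD per kind of RNA (bars). All 17 libraries lie above 0, from 1.17 to 1.52 at 14Rik, 0.86 to 1.30 in Pou5f1 total RNA, 0.41 to 0.52 on chromatin and 0.29 to 0.43 in run-on RNA.

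Spliced reads took a smaller share of nascent and chromatin-bound RNA than of steady-state RNA. Over 1869 inserts with enough reads in all 8 untreated Pou5f1 libraries, the median spliced share of an insert was 34.2% ± 10.6 (SD, n = 4) in total RNA and 7.30% ± 1.53 (SD, n = 4) in run-on and chromatin RNA pooled. The lowest total RNA library (23.1%) stood above the highest of the other kind (9.52%). An exact permutation test over 70 regroupings gave a two-sided p = 0.0286, the smallest it can give. Pooling the 2 kinds was chosen after seeing the data, and libraries of one screen are not independent. No gDNA library (14) and no sorted or unsorted cell library (15) carried a spliced read, but these were aligned to unspliced references only, so this is no measured background.

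Few single inserts passed the test of a higher spliced share. Against run-on RNA, 5 of 1843 inserts had a higher spliced share in total RNA and none a lower one (581 at an unadjusted p under 0.05; 288 called by limma on log shares). Among them was sequence_03644, which went from 0 of 25088 reads, where 3 reads would be 0.012%, to 1.01% ± 0.25 (SD, n = 4, adjusted p = 0.0404, edgeR). Another was sequence_12457, from 24.6% ± 4.78 (n = 2) to 98.0% ± 1.18 (n = 4; same adjusted p). Against chromatin RNA, 1 of 1750 was called (464 at an unadjusted p under 0.05; 24 by limma), sequence_12527, from 76.4% ± 3.01 (n = 2) to 100.0% ± 0.009 (n = 4; adjusted p = 0.0418, edgeR). Leaving out any 1 of the 6 libraries ended all 5 run-on calls. Without total RNA replicate 2, the chromatin comparison gave 24 calls, and without any 1 of the other 5 libraries 0.

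The inserts differed in how completely they were spliced. In total RNA at Pou5f1, of 2020 inserts with at least 20 reads in every library, 468 had a mean spliced share over 90% and 281 under 1%. In 8 inserts every read in all 4 libraries was spliced, among them sequence_12531 with 21448 reads and sequence_12275 with 11790. In 152 inserts no library had a spliced read.

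**Figure D2:**
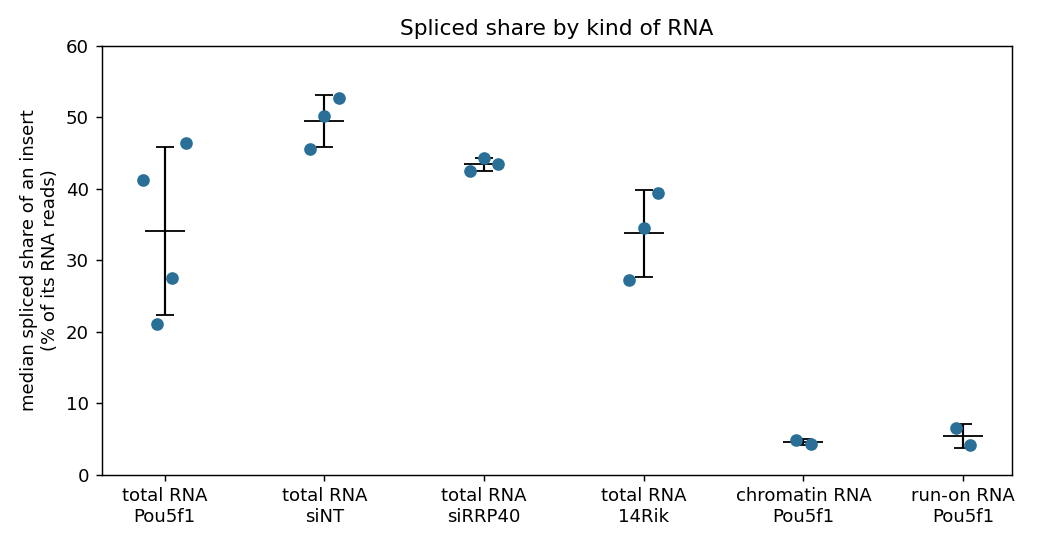
Median spliced share of an insert, in percent of its RNA reads, in each of the 17 RNA libraries (points; inserts with a spliced reference and at least 20 reads in that library), with the mean and SD per kind of RNA (bars). Chromatin and run-on libraries lie between 4.16% and 6.59%, and the 13 total RNA libraries between 21.0% and 52.7%.

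RNA on chromatin and nascent RNA also differed between inserts. Each had 2 libraries and was tested in a fit together with the total RNA and gDNA libraries. The SEs and p-values thus rest on a spread shared with those libraries, not on that of the 2 alone. Of 10616 inserts tested, chromatin RNA differed from the typical insert in 526 (378 higher, 148 lower). The highest was sequence_08500, with 102162 chromatin reads (log2 fold change 6.02, SE 0.72, adjusted p = 0.00413, edgeR quasi-likelihood test), and sequence_12550 again stood high (3.75, SE 0.31, adjusted p = 0.000291). For sequence_10940 and sequence_10736 neither chromatin library held a read, against 3268 and 5348 reads in the 5 gDNA libraries of the fit. With 0 set to 3 reads they were 353-fold and 577-fold lower on pooled reads. These folds are no lower bounds, since every count is even, and the pool includes gDNA of screens without chromatin RNA. Leaving out any 1 screen ended the call of sequence_10940 (adjusted p from 0.0512 to 0.13, edgeR). On unspliced reads alone sequence_12550 was no longer called (0.68, adjusted p = 0.659). The count was 302, 202 and 203 without screens 1, 2 and 4. The split turned to 50 higher and 152 lower without screen 2 and to 180 and 353 without screen 3. It was 780 and 779 by DESeq2 and 200 and 169 with library totals.

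Run-on RNA differed from the typical insert in 212 of 10616 inserts (145 higher, 67 lower). Here too sequence_12550 (log2 fold change 4.11, SE 0.34, adjusted p = 0.000294, edgeR quasi-likelihood test) and sequence_12189 (3.41, SE 0.65, adjusted p = 0.0332) stood highest. Among those that fell were sequence_03071, with 62 run-on reads against 3334 gDNA reads (-6.05, SE 1.30, adjusted p = 0.0404), and sequence_03824, with 30 against 3438 (-5.89, SE 1.17, adjusted p = 0.0294). These reads are summed over the 2 run-on libraries and over the 5 gDNA libraries of the fit, which include screens without run-on RNA. Both rises were lost on unspliced reads alone (adjusted p = 0.368 and 0.963). The call of sequence_12550 was lost without screen 4 (adjusted p = 0.0534), and those of the other 3 held without screen 3 alone. The count was 62, 44, 0 and 1 without screens 1, 2, 4 and 5, and 439 higher and 577 lower by DESeq2, 81 and 75 with library totals.

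The gap between the classes was smaller in both. Inserts with a spliced reference had a median log2 fold change of 0.36 on chromatin (130 of 1418 higher, 7 lower), against -0.15 for the rest (adjusted p = 2.46e-07 by camera, adjusted p = 0.0883 with an estimated correlation). In run-on RNA it was 0.24 (56 higher, 6 lower) against -0.09 (adjusted p = 0.00051, and adjusted p = 0.164 with an estimated correlation). Per screen the gap was 0.46 ± 0.08 on chromatin and 0.36 ± 0.10 in run-on RNA (SD, n = 2 each). On unspliced reads alone it was 0.05 and -0.01 (adjusted p = 0.56 and 0.991).

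Set directly against nascent RNA, steady-state RNA was higher at inserts with a spliced reference. Total RNA exceeded run-on RNA by a median log2 fold change of 0.70 in the class (139 of 1418 higher, 6 lower) and by -0.05 in the rest (289 of 9198 higher, 98 lower; adjusted p = 3.27e-08 by camera, adjusted p = 0.0861 with an estimated correlation). The median excess was 0.29, 0.25 and 0.29 in inserts under 1%, from 1 to 10% and from 10 to 50% spliced in siNT cultures (357, 164 and 267 inserts), and it was 0.91 from 50 to 90% (243 inserts) and 1.45 at 90% or more (335 inserts). Over all inserts, 532 differed, 428 higher and 104 lower in total RNA. The largest rises were those of sequence_02370, with 3364 total and 18 run-on reads (log2 fold change 6.54, SE 0.94, adjusted p = 0.00451, edgeR quasi-likelihood test), and sequence_12253 (5.80, SE 0.75, adjusted p = 0.00399). The largest falls were those of sequence_10957 (-4.56, SE 0.81, adjusted p = 0.0123) and sequence_08266 (-4.54, SE 0.90, adjusted p = 0.0195). Without screens 1, 2, 4 and 5 the count was 153, 349, 0 and 81, so that all 4 inserts were lost without screen 4, and sequence_10957 was also lost without screen 5, and sequence_08266 without screens 1 and 5. With library totals 176 were higher and 192 lower, and on unspliced reads alone the class gap turned to -0.18 (adjusted p = 0.0876).

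Against chromatin RNA, total RNA was likewise higher in the class, with a median log2 fold change of 0.58 against 0.09 for the rest (29 of 1418 and 24 of 9198 higher, 3 and 20 lower; adjusted p = 9.04e-06 by camera, adjusted p = 0.106 with an estimated correlation). Of all 10616 inserts 76 differed, 53 higher and 23 lower. For sequence_07702 and sequence_04826 the 2 chromatin libraries held 0 reads and the 4 total RNA libraries 1952 and 2614. With 0 set to 3 reads, total RNA was 201-fold and 269-fold higher on TMM-scaled library sizes. These folds are no lower bounds, since every count is even. In the other direction stood sequence_08266 (log2 fold change -5.34, SE 0.94, adjusted p = 0.0366, edgeR quasi-likelihood test) and sequence_08500 (-4.38, SE 0.63, adjusted p = 0.0306). No insert was called without screen 1, 4 or 5, 190 without screen 3, and sequence_07702 and sequence_08500 were lost without screen 2 (adjusted p = 0.115 and 0.105), as was sequence_08266 without screen 3 (adjusted p = 0.273). The call of sequence_08500 was also lost without the screen as a block (adjusted p = 0.0761). With library totals 55 were higher and 129 lower, and on unspliced reads alone 42 and 62, with a class gap of -0.30 (adjusted p = 0.0043).

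The same library was also read at 14Rik, in another chromosome and in cells without the Pou5f1 reporter. Of 14755 inserts tested, 6335 (42.9%) differed from the typical insert, 3608 higher and 2727 lower. The highest were sequence_11994, with 124132 RNA reads against 898 gDNA reads (log2 fold change 6.30, SE 0.39, adjusted p = 0.000405, edgeR quasi-likelihood test), and sequence_14233 (6.01, SE 0.35, same adjusted p), which has a spliced reference and fell to 0.01 on unspliced reads alone. Among those that fell was sequence_16275, with 6 RNA reads, all in 1 of 3 libraries, against 2984 gDNA reads (adjusted p = 0.00261). Inserts with a spliced reference had a median log2 fold change of 1.13 (1019 of 2091 higher, 158 lower), against -0.25 for the rest (2589 and 2569 of 12664). The gap per screen was 1.36 ± 0.18 (SD, n = 3; adjusted p = 2.71e-15 by camera, adjusted p = 0.0861 with an estimated correlation), and 0.05 on unspliced reads alone (adjusted p = 0.601). The count was 2777 without replicate 3, and 1804 higher and 4741 lower with library totals.

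Whether an insert behaved differently in the 2 loci was tested as an interaction. Of 10076 inserts, 226 did, 104 higher and 122 lower at 14Rik, and log2 RNA per gDNA correlated between loci with a mean Pearson r of 0.535 across inserts (range 0.448 to 0.624 over 12 pairs of libraries). At 14Rik sequence_11994 had 124132 RNA reads on 898 gDNA reads, and at Pou5f1 1040 on 5940 (log2 difference 9.73, SE 1.38, adjusted p = 0.00969, edgeR quasi-likelihood test). The reverse held for sequence_03477, with 12 RNA reads on 672 gDNA reads at 14Rik and 15312 on 3198 at Pou5f1 (-8.54, SE 0.77, adjusted p = 0.000561), and for sequence_06127 (-8.40, SE 1.33, adjusted p = 0.0103). The class of inserts with a spliced reference did not pass the test of a difference (median 0.00 against -0.06; adjusted p = 0.601 by camera, adjusted p = 0.791 with an estimated correlation; 0.25 and adjusted p = 0.0294 on unspliced reads alone). The call of sequence_11994 was lost without 14Rik replicate 3 (adjusted p = 0.0651), and that of sequence_06127 without it or without Pou5f1 replicate 1 (adjusted p = 0.0651 and 0.0817). The count was 59 without the screen as a block, 101 and 53 without 14Rik replicates 2 and 3, and 44, 61, 139 and 67 without Pou5f1 replicates 1, 2, 3 and 4. Locus, cell line and the place of the reverse transcription primer (221 nt downstream at Pou5f1, 287 nt at 14Rik) change together here.

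Splicing of single inserts also differed between the loci. Of 1757 inserts, 48 had another spliced share at 14Rik than in Pou5f1 total RNA, 4 higher and 44 lower (425 at an unadjusted p under 0.05; 157 called by limma on log shares). Over all 1757 inserts, 38.1% had a higher share at 14Rik, and the median log2 change of an insert was -1.09 (quartiles -3.61 to 1.34). The median share went the other way, at 48.4% ± 7.01 at 14Rik (SD, n = 3) and 46.2% ± 12.1 at Pou5f1 (SD, n = 4), a difference within the spread between replicates. At Pou5f1 sequence_01427 was 13.2% ± 6.80 spliced and sequence_09644 32.8% ± 8.92 (SD, n = 4). At 14Rik no read of 46120 and of 11606 was spliced, where 3 reads would be 0.0065% and 0.0258% (adjusted p = 0.0249 for both, edgeR quasi-likelihood test). In the other direction sequence_01765 went from 0 of 13262 reads at Pou5f1 (3 reads would be 0.0226%) to 4.88% ± 2.77 at 14Rik (SD, n = 3, adjusted p = 0.0286, edgeR). Likewise sequence_01435 went from 0 of 5674 (3 reads would be 0.0529%) to 6.01% ± 2.45 (adjusted p = 0.0446, edgeR). Such percentages of 3 reads are no upper limits, since every count is even and PCR reads without molecular identifiers are not independent molecules. No call was left without Pou5f1 replicate 1 or without any 14Rik replicate, the call of sequence_01435 was also lost without Pou5f1 replicate 2 (adjusted p = 0.0536, edgeR), and 83 inserts were called without Pou5f1 replicate 4.

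RRP40 (Exosc3) is a subunit of the RNA exosome, a complex that degrades RNA in the nucleus and the cytoplasm, many non-coding transcripts among it, and its knockdown asks which inserts it limits. The files hold insert reads alone, so the knockdown of Exosc3 itself was not analysed here. Relative to siNT, inserts with a spliced reference had less RNA than the others after siRRP40, by a median log2 fold change of -0.17 (1328 inserts) against 0.02 (8484 inserts; adjusted p = 0.000182 by camera, adjusted p = 0.0189 with an estimated correlation). The gap between the classes was 1.13 ± 0.08 in siNT and 0.99 ± 0.02 in siRRP40 cultures (SD, n = 3 each), lower in all 3 siRRP40 cultures than in any siNT culture. An exact permutation test of 3 against 3 gave a two-sided p = 0.1, the smallest it allows. A narrower range of levels over inserts in the siRRP40 cultures, given below, would by itself make the gap between the classes smaller. The class was lower without any 1 of the 6 cultures too (adjusted p from 6.62e-05 to 0.00186), but not on unspliced reads alone, where the class difference was -0.04 (adjusted p = 0.601).

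The change after siRRP40 also varied with how much RNA an insert yields. In 5 bands of equal size by RNA per gDNA in the untreated Pou5f1 screens, the median log2 change of inserts without a spliced reference went from 0.23 in the lowest band through 0.09, -0.02 and -0.04 to -0.08 in the highest. For inserts with one it went from 0.17 through -0.00, -0.14 and -0.15 to -0.29. Across 6947 inserts without a spliced reference, change and level correlated with a Spearman rho of -0.196, and across 997 with one with -0.243. The SD of log2 RNA per gDNA over inserts was also smaller in siRRP40 (1.87 to 1.92) than in siNT cultures (2.04 to 2.06). A narrower range of levels alone would give a rise at low and a fall at high levels. An effect of the level itself was not told apart from it. The split by level was not part of the design fixed before the data were examined.

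A single insert passed the test of siRRP40 against siNT out of 9812. It was sequence_12853, which has a spliced reference, with a log2 fold change of -2.15 (SE 0.33, adjusted p = 0.0401, edgeR quasi-likelihood test). It had 32446 RNA reads on 1118 gDNA reads in siRRP40 and 61266 on 352 in siNT cultures, so most of the change came from its gDNA (1.49, against -0.70 in the RNA libraries alone). An unadjusted p under 0.05 was reached by 844 inserts, and DESeq2 called 58 (32 higher, 26 lower). On simulated data this comparison recovered 64.2% of inserts changed 4-fold and 2.99% of those changed 2-fold. No insert was called without siNT replicate A or B or siRRP40 replicate A or B, and 2 without siRRP40 replicate C. None was called without the culture as a block either.

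No single insert passed the test of another spliced share after siRRP40. The median share over 1633 inserts was 64.6% ± 1.37 in siRRP40 and 69.5% ± 2.46 in siNT cultures (SD, n = 3 each). All 3 siRRP40 libraries (63.4% to 66.1%) lay below all 3 siNT libraries (66.7% to 71.1%), which chance gives in 10% of cases for 3 against 3. The median log2 change of an insert was -0.33, and 35.3% of inserts had a higher share after siRRP40. With edgeR's quasi-likelihood test 0 inserts were called, 113 had an unadjusted p under 0.05, and limma on log shares called 0. On simulated data 70.1% of 4-fold changes in the odds of splicing were recovered and 5.97% of 2-fold ones.

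**Figure D3:**
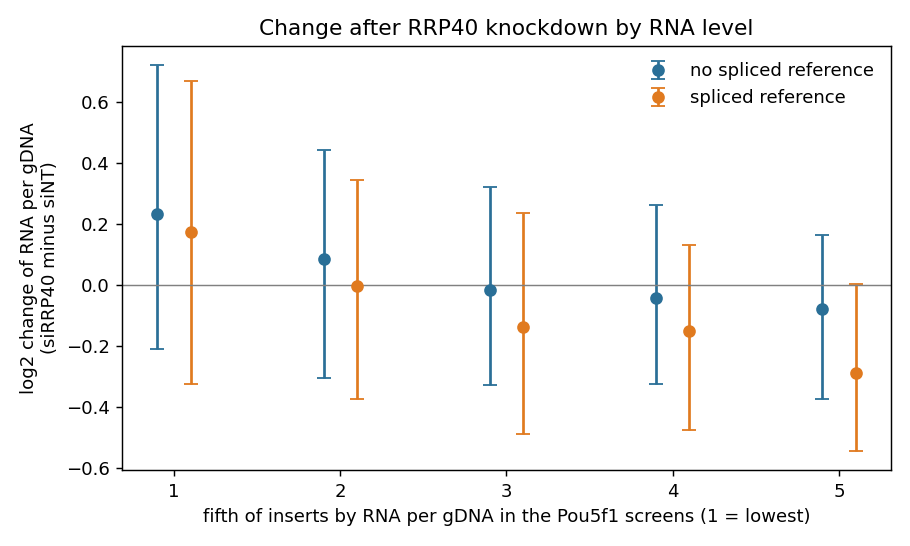
Log2 change of RNA per gDNA, siRRP40 minus siNT, for 5 equal bands of inserts by RNA per gDNA in the untreated Pou5f1 screens (1 is the lowest). Points are medians over inserts and bars the quartiles. Medians go from 0.23 to -0.08 without and from 0.17 to -0.29 with a spliced reference.

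Sort-seq reads the fluorescence of the cells that carry an insert from gDNA alone. Of 10229 inserts, 4235 (41.4%) changed in abundance along bins 1 to 6, 2903 upward and 1332 downward in bin number, all with 1 sign in both screens. The 6 bins of a screen are parts of 1 sorted population, and the fit counts them as separate libraries. Its p-values therefore rest mostly on the scatter of bins around a line, with only 2 independent screens. The labels do not state how bin number relates to brightness. In both screens sequence_03356 and sequence_02533 sat almost wholly in bin 6 (mean bin 6.00 and 5.99 for each; slopes 5.16 and 4.87 log2 units per bin, SE 0.51 and 0.52, adjusted p = 1.76e-08 and 6.02e-08, edgeR quasi-likelihood test). At the other end were sequence_09400 (mean bin 1.28 and 1.11; slope -4.30, SE 0.81, adjusted p = 6.12e-05) and sequence_06912 (1.27 in both; -3.88, SE 0.75, adjusted p = 7.81e-05). The mean bin of an insert correlated between screens with a Pearson r of 0.926 across inserts. The count was 1284 without screen 2 (1185 upward, 99 downward) and 1070 of 1874 (534 upward, 536 downward) at 200 reads unsorted and 400 over the bins. The split was 2251 upward and 2729 downward with library totals and 3675 and 3776 by DESeq2, which moved the median slope of all inserts from 0.38 to -0.37 and -0.13.

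Inserts with more RNA sat in higher bins. The mean bin correlated with log2 RNA per gDNA with a Spearman rho of 0.444 to 0.553 across inserts for Pou5f1 total RNA, 0.427 to 0.482 for 14Rik, 0.304 to 0.334 for chromatin RNA and 0.123 to 0.326 for run-on RNA (ranges over pairs of libraries). Inserts with a spliced reference had a median mean bin of 3.90 and 3.95 in the 2 screens and the others 3.09 and 3.23. Of 1365 tested inserts of the class 596 rose and 89 fell along the bins, against 2307 and 1243 of 8864 (p = 4.09e-05 by camera, p = 0.167 with an estimated correlation). Mean bins were highest for mostly spliced inserts: in screen 1 the median mean bin was 3.45 under 1% spliced, 3.47 from 10 to 50% and 5.39 at 90% or more, and in screen 2 it was 3.49, 3.44 and 5.42.

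**Figure D4:**
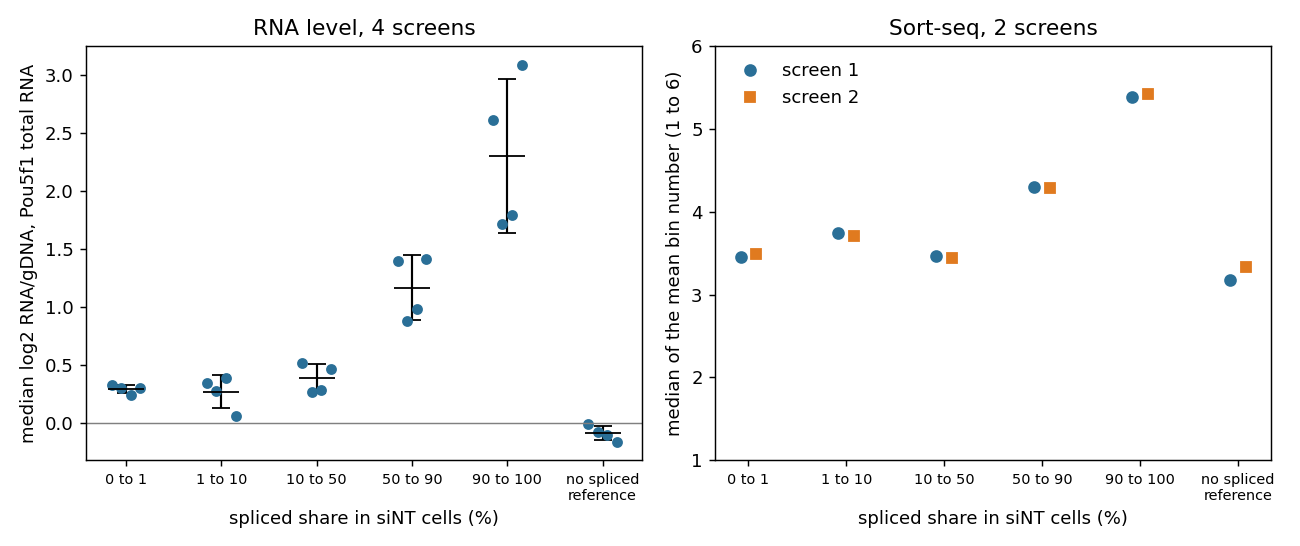
Inserts grouped by their spliced share in siNT cells (percent). Left, the median log2 RNA per gDNA in each of 4 Pou5f1 total RNA screens (points) with mean and SD (bars), from a mean of 0.29 under 1% to between 1.71 and 3.08 at 90% or more. Right, the median of the mean bin number (1 to 6) in sort-seq screens 1 and 2, from 3.45 and 3.49 to 5.39 and 5.42.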

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

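The tests of RNA stability, of inserts under 1% spliced against amplicon length, of the size of carried template, and of the regrouped samples at Pou5f1, at 14Rik, between the loci and for siRRP40 were chosen only after the result was seen, and 1 criterion of the gDNA test was set aside afterwards, as stated beside it.

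In Pou5f1 total RNA, replicate 4 had 45.7% of its reads without a reference and lay far below the other 3 replicates (52.8% to 53.0%) and near the siNT libraries (46.2% to 46.7%), the only 1 of 28 ends tested in 14 series, where chance alone gives about 1 in 20 groups. The effect of an insert differed between the 14Rik and Pou5f1 loci for 226 inserts by a test of the difference itself. It differed between siRRP40 and siNT cultures for 1 insert, and for the class with a spliced reference with an adjusted p of 0.000182 (camera).

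Inserts with a spliced reference had more RNA per gDNA than the others. Against better amplification of shorter spliced amplicons, inserts under 1% spliced, which have almost only full-length amplicons, still lay above inserts without a spliced reference by 0.38, in all 4 Pou5f1 screens. For the more spliced inserts amplicon length stays open: the class gap in mean bin, read from unspliced gDNA, was at least 0.72 in both screens, but the level also correlated with the nt removed (Spearman 0.04 to 0.21 over 4 Pou5f1 screens). Whether spliced forms were found only at inserts with many RNA reads stays open. The level correlated with the siNT spliced share in every screen (lowest Spearman 0.354). This trend within the class does not tell why the class lies above the others, and the level itself counts spliced reads. Inserts under 1% spliced do not decide it either, since their gDNA reads were 0.976 of those of the others (95% bootstrap interval 0.897 to 1.05). A candidate explanation is that spliced RNA is more stable, since the excess of total over run-on RNA correlated with the siNT spliced share (Spearman 0.42), but RNA decay was not measured, and the excess was level below 50% spliced. Levels count spliced reads, which took a larger share of total than of run-on RNA. Better amplification of shorter spliced amplicons could therefore give the same correlation, which does not tell it apart from stability.

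After siRRP40, inserts with a spliced reference had less RNA per gDNA relative to the others. A difference between gDNA libraries as the whole cause is argued against by the RNA libraries alone, where the class difference was -0.15; the planned criterion also asked for a gDNA difference under 0.25 of the effect, which failed (0.05, against -0.14 per gDNA), and it was set aside after this was seen, because it bears on a part of the effect and not on the RNA alone, so that a contribution of gDNA stays open. Template carried into the siRRP40 libraries would raise their lowest levels, as was seen (the lowest siRRP40 culture lay 0.17 above the highest siNT culture at the 1st percentile), but the amount this allows gives a change of at most -0.0413. A rise of low-level RNA after loss of the exosome may account for part, since the change fell with the RNA level also among inserts without a spliced reference (Spearman -0.196). The narrower range of levels in the siRRP40 cultures would give the same trend and also a smaller gap between the classes. It was not told apart from such a rise or from an effect on the class. Matched on level, the class difference was -0.13, against -0.19 unmatched. That level came from the untreated Pou5f1 screens, varied between them and counts spliced reads. Matching on it may correct too little, so the difference left does not show an effect of the class beyond the level.

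Reads without a reference took a larger share in bins 1 and 2 than in unsorted cells (51.0% to 52.2%): 54.6% and 53.8% in screen 1 and 53.4% and 55.0% in screen 2. The share fell with bin number (Spearman -1 and -0.943 over 6 bins). Library size is argued against, since its correlation with the share had opposite signs, -0.0857 in screen 1 and 0.371 in screen 2. What these reads are was not analysed, and no biological explanation was tested.

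Other splits of the same samples were counted for the comparisons with at least 3 samples per group. For Pou5f1 total RNA, RNA and gDNA are paired by screen, and the 8 splits that part every pair are too few for a share under 0.05 (2963 calls without the block, highest other of the 8 at 0, and 10 among all 35 splits, 1 of which, the real one, had as many). For the loci, only the real split of 35 had as many calls (226 against 0), and so for spliced shares between the loci (48 against 0). The other splits mix the loci within a group, which can itself lower their calls. Leaving out 1 replicate gave as few as 44 and 0 calls, so chance is not excluded. For 14Rik (5866 calls, highest other 0), siRRP40 (1, highest other 0) and spliced shares after siRRP40 (0, highest other 0), the 10 splits are too few for a share under 0.05.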

How the results depend on the processing

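Counts halved to read pairs were the alternative chosen after seeing the data. A named insert was followed once per comparison it was named in, which gave 40 results. Of 481 pairs of such a result and a setting, 368 kept direction and call, 110 kept direction alone and 3 reversed. Where no cause is given below, the cause was not tested.

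At 200 reads as the minimum, with fewer inserts tested, the calls numbered 1644 for Pou5f1 total RNA, 213 for total against chromatin RNA, 118 between loci, 9 for siRRP40 and 1070 for sort-seq. The agreement between libraries was then 0.709 for Pou5f1, 0.404 for run-on, 0.912 for siNT, 0.909 for siRRP40 and 0.431 for chromatin RNA. At 10 reads they numbered 123 for run-on RNA, 39 and 326 for total against chromatin and run-on RNA, 138 between loci and 0 for siRRP40. With no filter they were 106, 19, 221 and 81, and the class test between loci reversed (adjusted p = 0.774). DESeq2 called 1559 for chromatin and 1016 for run-on RNA, 991 and 1343 for total against each, 897 between loci, 58 for siRRP40 and 7451 for sort-seq. Library totals gave 184 for total against chromatin RNA and 0 for siRRP40. For siRRP40, unspliced reads alone, the deposited ratios in limma, the letter as a replicate block and gDNA alone gave 0 and RNA alone 5.

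Without the screen as a block 59 inserts were called between loci and 0 for siRRP40. The other counts without the block, or pairing, were 2963 for Pou5f1, 464 for chromatin, 235 for run-on, 53 and 520 for total against chromatin and run-on RNA, 5866 for 14Rik and 4380 for sort-seq. Without a replicate block limma on log shares called 288 against run-on RNA, 24 against chromatin RNA and 157 between loci. With at least 5 reads, 3 spliced shares were called against chromatin RNA. Mean bins weighted by read totals correlated at 0.92.

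On unspliced reads alone the class test gave adjusted p = 0.226 for Pou5f1, 0.56 for chromatin, 0.991 for run-on, 0.0043 and 0.0876 for total against chromatin and run-on RNA, 0.601 for 14Rik, 0.0294 between loci and 0.601 for siRRP40. With an estimated correlation it gave adjusted p = 0.0861 for Pou5f1, 14Rik and total against run-on RNA. It gave adjusted p = 0.0883 for chromatin, 0.164 for run-on RNA and 0.106 for total against chromatin RNA. In these comparisons the inserts without a spliced reference, the other side of the same split, were lower (adjusted p from 0.0114 to 0.0189 by camera with an estimated correlation). The outcome thus depended on which side was tested. For siRRP40 the class test held. On gDNA alone the siRRP40 class reversed (adjusted p = 0.78), as did sequence_12853 (1.49). On unspliced reads alone sequence_12550 (-1.79) and sequence_12189 (-3.78) reversed.

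Leaving out 1 replicate, the calls ranged from 2678 to 4235 for Pou5f1, 202 to 533 for chromatin, 0 to 244 for run-on, 0 to 190 for total against chromatin RNA, 0 to 616 for total against run-on RNA, 2777 to 7425 for 14Rik, 44 to 236 between loci, 0 to 2 for siRRP40, 1284 to 3261 for sort-seq and, for spliced shares, 0 to 0 against run-on RNA, 0 to 24 against chromatin RNA and 0 to 83 between loci. The class test between loci ranged from adjusted p = 0.174 to 0.997. A lone library left in an arm is assumed to vary like the others. Sequence content, gene lists and mutated against native inserts were not run, since the files do not pair insert numbers with sequences.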

Other observations

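Inserts with 2 or more spliced references were tested as a class of their own; they were not compared with the other inserts that have a spliced reference. At Pou5f1, 39 of 99 were higher than the typical insert and 11 lower, with a median log2 fold change of 0.43 (adjusted p = 0.00237 by camera, adjusted p = 0.0649 with an estimated correlation). At 14Rik, 61 of 125 were higher and 10 lower, with a median of 1.11 (adjusted p = 2.95e-06, and adjusted p = 0.141 with an estimated correlation). Total RNA exceeded run-on RNA at these inserts by a median of 0.77 (adjusted p = 0.000735, and adjusted p = 0.0799 with an estimated correlation). On chromatin 8 of 99 were higher and 0 lower (median 0.24, adjusted p = 0.00237, and adjusted p = 0.0883 with an estimated correlation). The class did not pass the test in run-on RNA (median 0.20, mean -0.11, adjusted p = 0.601), for total against chromatin RNA (median 0.30, adjusted p = 0.21), between loci (median 0.23, adjusted p = 0.0613) or after siRRP40 (median -0.11, adjusted p = 0.397).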
